A study of Mus musculus with 6 samples.

How the data were processed

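Total RNA was taken from 3 flasks of AB1 cells and 3 flasks of AC29 cells, both mouse malignant mesothelioma lines, per the labels. Biotinylated cRNA was made from 5 ug of total RNA and hybridised to an Affymetrix 3′ expression array, 1 array per flask, per the labels' protocols. The deposited table held a single log2 value per probe set and array for 45101 probe sets. The submitters' processing notes name GCOS, RMA and Partek 6.4, with no role or order given for each; RMA is a method that corrects background, normalizes arrays by quantiles and summarises the probes of a set on the log2 scale. The scale of the deposited values was taken as log2 from their range and from these notes. RMA pulls the values of dim probe sets together and flattens bright ones, so that differences of very low or very high genes can be understated. Scan dates, detection calls and probe-level intensities were not analysed here, so no scan batch could be tested.

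The array's controls, 64 probe sets, were left out. Gene names came from the platform's annotation: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none in that table. Through the Entrez identifier, 34741 of the single-symbol probe sets matched the RefSeq gene table, and 0 symbols had to be updated. A gene was represented by its single-symbol probe set with the highest mean over the 6 arrays, which gave 18193 genes, of which 9010 had more than 1 such probe set. No probe set with several symbols was given a gene name.

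Differences were AC29 minus AB1. A linear model with line as its only term was fitted to every probe set outside the controls with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), and p-values were adjusted over the 18193 genes by the method of Benjamini and Hochberg. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The residual degrees of freedom were 4 and the moderated total was 8.92. Folds were computed from differences of mean log2 values. The floor was the 95th percentile, 6.07, of the values of 86 olfactory, vomeronasal and taste receptor probe sets, which cultured mesothelioma cells are not expected to express. Where all 3 arrays of a line were at or under it, the fold was computed against the floor as a lower bound, and no fold was given where that held for both lines. Intervals and errors are the SD over 3 arrays or the standard error from limma. No depth applies to array values; the number of arrays limits the precision.

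Before the data were examined, 36 gene lists with 871 distinct genes were fixed, of which 809 were measured. They cover mesothelial, epithelial, mesenchymal, matrix, protease, adhesion, MHC class I and class II, interferon, cytokine, checkpoint, growth factor, mesothelioma driver, Hippo, p53, cell cycle, glycolysis, hypoxia, oxidative phosphorylation, cholesterol, unfolded protein, Nrf2, Wnt, TGF-beta and BMP, homeobox, lineage transcription factor, imprinted, cancer-germline, drug transport and sex-linked genes, and markers of macrophages, lymphocytes, endothelium, fibroblasts, muscle and nerve. The 35 lists with at least 5 measured genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Genes were named by a rule fixed at the same time: the 12 largest differences in each direction among called genes whose arrays did not overlap, leaving out symbols that are clone or model names; in each list up to 4 called genes per direction and the 2 brightest genes not called; every measured mesothelioma driver, sex-linked and MHC class II gene; and Csf1, Csf2, Il34, Ccl2, Il6, Cd274, B2m, Msln, Wt1, Calb2, Cdh1 and Vim. Any gene of a fixed list was also open to naming where a pattern was weighed.

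The model was tested on simulated data drawn from the real means and residual spreads of the AC29 and AB1 comparison, with 18193 genes of which 50 were changed per size. At simulated log2 changes of 1, 1.5, 2 and 4, 40%, 96%, 98% and 100% were called in the right direction, the first being at the minimum difference itself. None of 17993 unchanged genes was called, and 95.5% of the changed genes lay inside their 95% interval. A simulated list shift was found by camera, with 0 of 35 unchanged lists called. The simulated genes were drawn independently of each other, so this cannot tell whether the preset correlation holds for the real lists. The chromosome comparison of the closing section, run on 7522 genes with shuffled chromosomes and 1 of them shifted, found that chromosome and none of the 19 others.

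The alternatives tried were quantile normalization, centring of the arrays on all probe sets or on the brightest genes, 2 filters on dim genes, the mean of a gene's probe sets, every probe set on its own, leaving out probe sets marked for cross-hybridisation, eBayes with trend and robust settings, array weights, limma's treat, an unmoderated fit, other thresholds, other gene list tests, other percentiles for the floor and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.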

Results

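Total RNA of 2 mouse malignant mesothelioma cell lines was profiled on an Affymetrix 3′ expression array. Malignant mesothelioma is a tumour of the lining of the body cavities, and both lines were induced with asbestos. AB1 comes from a BALB/c mouse and was grown to passage 40, and AC29 comes from a CBA mouse and was grown to passage 60. Each line was sampled from 3 flasks at 80% confluency with 1 array per flask, so that p-values measure the spread between flasks of a line. Line, strain, passage and any processing batch coincide in this design and cannot be told apart. The deposited values were log2 RMA intensities, whose median per array lay between 5.76 and 5.81. Across genes, Pearson's r was between 0.997 and 0.998 within AB1, between 0.995 and 0.997 within AC29 and between 0.937 and 0.938 between the lines. The first principal component held 93.1% of the variance and separated the lines. The second held 2.86% and set AC29 replicate 14 apart, an array whose probe set for the middle of 18S rRNA read 8.53 against 7.43 to 7.91 on the others. A floor of 6.07 was taken from 86 probe sets of olfactory, vomeronasal and taste receptor genes, and a fold against a line in which no array exceeded it is given as a lower bound. The number of arrays limits the precision; the median standard error of a difference was 0.0999 on the log2 scale.

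Among the genes with the largest differences were the keratins Krt14 and Krt8 on the AC29 side and the smooth muscle actin Acta2 and the secreted antagonist Grem1 on the AB1 side. Fabp5, a fatty acid binding protein, read 12.27 ± 0.09 (SD, n = 3) in AC29 against 3.16 ± 0.12 in AB1, which is at least 73.6-fold. Krt14, found in basal epithelium, was at least 141-fold higher in AC29 (13.21 ± 0.10 against 4.97 ± 0.29), and Krt8, found in simple epithelium, at least 120-fold. Grem1, which binds bone morphogenetic proteins, read 12.72 ± 0.03 in AB1 against 4.91 ± 0.15 in AC29, at least 99.9-fold. Acta2 was 104-fold higher in AB1 (13.22 ± 0.03 against 6.53 ± 0.16), and Col4a1, a chain of basement membrane collagen, at least 61.1-fold. The other genes with the largest differences of mean log2 values toward AC29, whose order rests on values under the floor, were Gpm6a (at least 56.5-fold), Frmd4b (36.5), Tspan8 (27.6), Stk26 (28.8), Tmem98 (91.4), Upk3b (86.9), Bnc1 (26.3), Zic1 (18.1) and Gsta4 (102). Those toward AB1 were Prkar2b (at least 32.8-fold), the urea transporter Slc14a1 (27.8), the Wnt modulator Dkk2 (23.6), Dpysl3 (38.2), Bmp2 (21.8), B3galnt1 (12.1), Trbv1 (14.0), Foxc2 (21.1) and the phosphatase Ptpn22 (16.1). Trbv1 is a segment of the T-cell receptor beta locus with many related copies, so its probe set is uncertain.

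Of 18193 genes, 1991 passed the call rule of an adjusted p under 0.05 in limma and at least a 2-fold difference, 932 higher in AC29 and 1059 higher in AB1. In 1990 of them the arrays of the lines did not overlap; over all genes tested the share without overlap was 50.1%, against 10% by chance. At least 4-fold differences were found for 723 called genes and at least 16-fold differences for 176. AB1 was not above the floor for 314 of the genes higher in AC29, and AC29 for 317 of those higher in AB1. A further 84 called genes were not above it in either line. They include Cdh1, Nlrc5, Tslp, Arg2, Mmp13 and Aldh3a1, which enter the counts of their gene lists below. The 180 called genes among the 275 that the naming rule took had adjusted p-values of at most 0.000344, and the standard errors of the 275 differences ran from 0.0761 to 0.324. Without the 2-fold minimum 7105 genes passed, and 1237 passed when limma tested against a 2-fold difference. Among 886 called genes with another probe set above the floor, 96.7% of 1423 such probe sets moved in the direction of the call. The rule itself was passed by 967 of the 1423 in that direction and by 2 in the opposite direction.

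**Figure D1:**
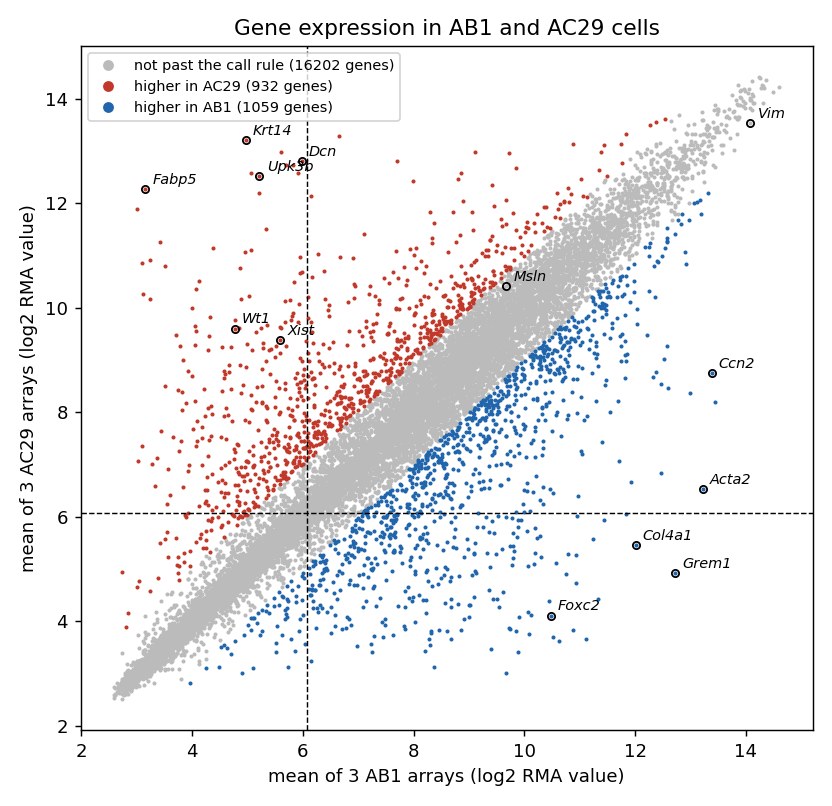
Mean log2 RMA value of the 3 AB1 arrays (horizontal axis) against the 3 AC29 arrays (vertical axis) for each of 18193 genes, with the 932 genes called higher in AC29 in red, the 1059 called higher in AB1 in blue and the floor of 6.07 as dashed lines. Fabp5 stands at 3.16 and 12.27 and Grem1 at 12.72 and 4.91, while Vim lies near the diagonal at 14.08 and 13.53.

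Genes of mesothelial cells, the lining cells from which the tumour arises, were higher in AC29. Of 20 measured members of the mesothelial list, 15 were higher in AC29, 1 was higher in AB1 and 4 did not pass, and 10 of the 15 were not above the floor in AB1. Wt1, a transcription factor used as a mesothelioma marker, read 9.59 ± 0.10 (SD, n = 3) in AC29 and 4.77 ± 0.23 in AB1, at least 11.5-fold. Upk3b, a uroplakin of mesothelium, read 12.51 ± 0.13 and 5.22 ± 0.21. Thbd, the thrombin receptor thrombomodulin, went the other way and was at least 7.69-fold higher in AB1. Msln, which encodes mesothelin, was present in both lines at 10.41 ± 0.23 and 9.67 ± 0.10, and Calb2, which encodes calretinin, read 6.58 ± 0.31 and 6.43 ± 0.06; neither passed the rule. Camera with its preset correlation placed the list toward AC29 (adjusted p = 1.51e-11). With an estimated correlation the adjusted p = 0.0588.

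Most of the mesenchymal genes past the rule were higher in AB1. Of 25 measured members, 12 were higher in AB1 and 2 higher in AC29 (camera adjusted p = 1.60e-05 toward AB1; adjusted p = 0.190 with an estimated correlation). Foxc2, a forkhead transcription factor, was at least 21.1-fold higher in AB1, Twist2, a transcription factor of mesenchyme, 8.46-fold (11.29 ± 0.07 against 8.21 ± 0.16, SD, n = 3), and Pdgfrb, a receptor for platelet-derived growth factor, at least 8.21-fold. Cdh11, a cadherin of mesenchymal cells, was at least 2.97-fold higher in AC29, and the smooth muscle calponin Cnn1 3.06-fold. Vim, the intermediate filament vimentin, was among the brightest genes in both lines at 14.08 ± 0.05 in AB1 and 13.53 ± 0.10 in AC29. In the epithelial junction list, 3 of 25 measured genes were higher in AC29 and none in AB1 (camera adjusted p = 0.295). Jup, which encodes plakoglobin, was 9.20-fold higher in AC29, and the splicing regulator Esrp2 read 8.47 in AC29 and 6.03, near the floor, in AB1. Cdh1, which encodes E-cadherin, passed the rule but read 3.89 in AC29 and 2.80 in AB1 and was not above the floor in either line.

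**Figure D2:**
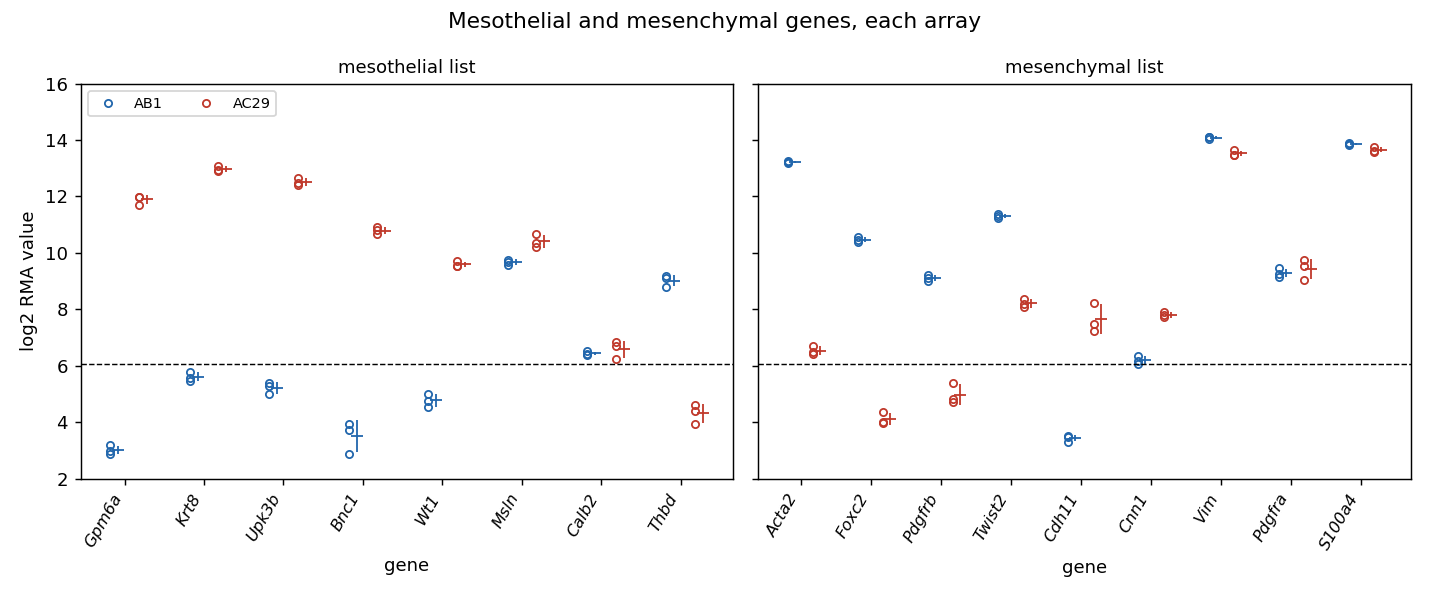
Log2 RMA value of each array (open circles), with the mean and SD of 3 arrays beside them, for named genes of the mesothelial list (left) and the mesenchymal list (right) in AB1 (blue) and AC29 (red); the dashed line is the floor of 6.07. The AB1 arrays of Upk3b average 5.22 and the AC29 arrays 12.51, while for Acta2 the AB1 arrays average 13.22 and the AC29 arrays 6.53.

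Matrix genes went in both directions. Decorin (Dcn), a small proteoglycan that binds collagen, was higher in AC29 (12.81 ± 0.07 against 5.98 ± 0.15, near the floor, SD, n = 3), as were the collagen VI chains Col6a2 at 12.7-fold and Col6a1 at 7.05-fold. The collagen IV chains Col4a1 and Col4a2 (at least 29.1-fold), the collagen crosslinking enzyme Loxl1 (at least 25.6-fold) and the thrombospondin Thbs2 (at least 14.2-fold) were higher in AB1. The fibrillar chains Col1a2 (13.88 in AC29 and 13.44 in AB1) and Col5a2 (13.15 and 12.45) did not pass the rule by their brightest probe sets, but did on the mean of their probe sets (log2 differences of 1.09 and 1.61). In all, 6 of 32 measured collagen and matrix genes were higher in AC29 and 9 higher in AB1 (camera adjusted p = 0.621). Fbln1 was at least 3.41-fold higher in AC29 by its brightest probe set, while another of its probe sets differed by -0.14 on the log2 scale (adjusted p = 0.357). Among 25 matrix proteases and inhibitors, 4 were higher in AC29, led by the protease inhibitor Timp3 at 98.8-fold, and 8 higher in AB1, led by the gelatinase Mmp2 at least 13.1-fold (camera adjusted p = 0.434). Timp1, another inhibitor, was 3.17-fold higher in AB1. Of 27 adhesion genes, 5 were higher in AC29 and 4 in AB1 (camera adjusted p = 0.621); Cd24a was at least 15.2-fold and Vcam1 7.95-fold higher in AC29, and the integrin chain Itga6 was 2.46-fold higher in AB1. The hyaluronan receptor Cd44 read 12.27 in AB1 and 11.24 in AC29, a 2.03-fold difference that fell under the 2-fold minimum without AB1 replicate 5 (-0.998) or AC29 replicate 15 (-0.975). Its other probe sets above the floor differed by -1.65 and -1.59 on the log2 scale.

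**Figure D3:**
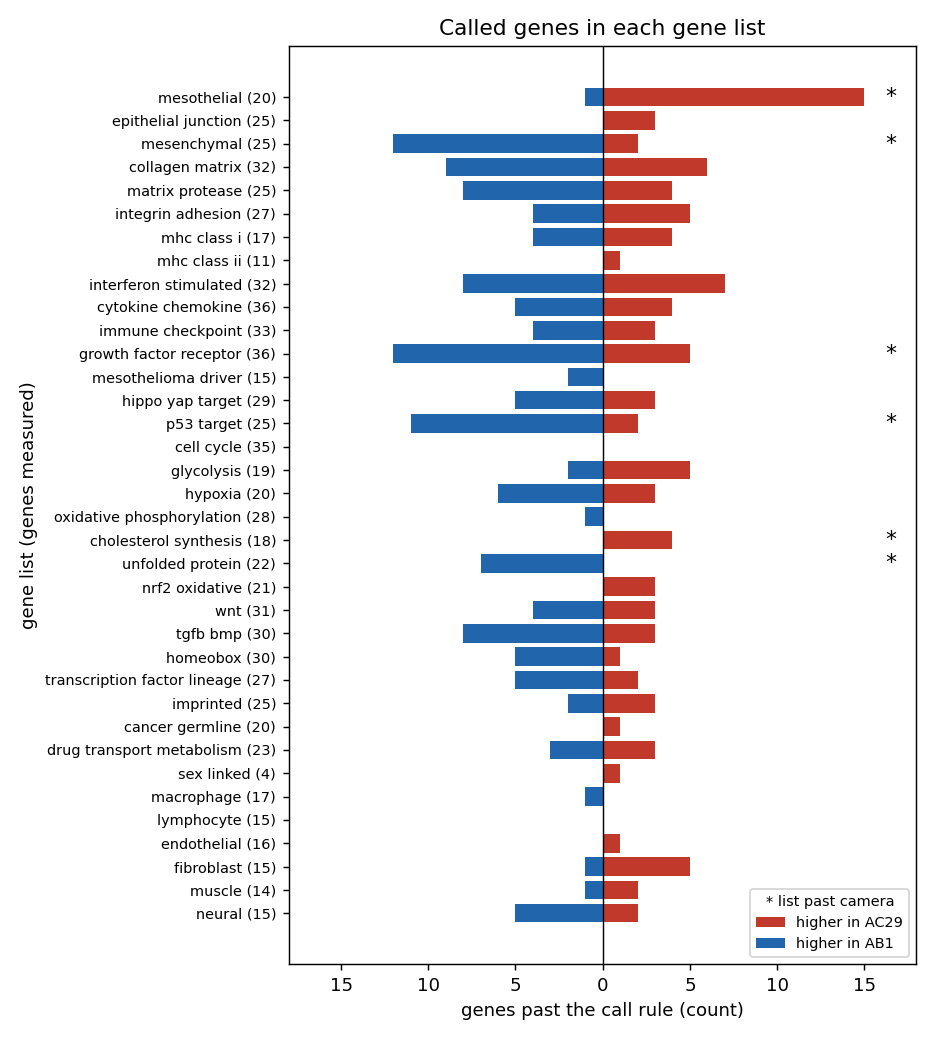
Number of genes past the call rule (horizontal axis) in each of 36 gene lists (vertical axis, genes measured in brackets), higher in AC29 to the right in red and higher in AB1 to the left in blue; a star marks a list past an adjusted p of 0.05 in camera with its preset correlation. The mesothelial list has 15 genes to the right and 1 to the left, and the mesenchymal list 2 and 12.

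Genes of antigen presentation, interferon response and secreted immune signals differed gene by gene and not in a common direction. In the MHC class I list, 4 of 17 measured genes were higher in AC29 and 4 higher in AB1 (camera adjusted p = 0.845). Nlrc5, counted toward AB1, was not above the floor in either line (5.71 in AB1 and 4.25 in AC29). Tapbp, which encodes the peptide loading protein tapasin, was 8.85-fold higher in AC29, and the immunoproteasome subunit Psmb10 2.82-fold. Tap1, a peptide transporter, was 2.20-fold higher in AB1, but not past the rule on the mean of its probe sets (-0.38). B2m, the invariant light chain, read 12.95 ± 0.03 (SD, n = 3) in AB1 and 12.67 ± 0.03 in AC29 and did not pass the rule. The class I heavy chains H2-K1 and H2-D1 were 4.61-fold and 5.54-fold higher in AB1 by their brightest probe sets; of 8 probe sets for H2-D1 above the floor, 7 were lower in AC29 past the rule and 1 was higher in AC29 by at least 5.42 on the log2 scale. In the MHC class II list 1 of 11 genes passed, the lysosomal reductase Ifi30 at 2.14-fold higher in AC29 (camera adjusted p = 0.621). H2-Aa, H2-Ab1, H2-DMa, H2-Oa, H2-Ob, Ciita and Ctss were not above the floor in either line, and H2-Ea, H2-Eb1 and Cd74 differed by at most 0.21. The means of these last genes, 6.03 to 7.21, lay under the 99th percentile of the receptor probe sets, 7.23, so they were near background.

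Interferon-stimulated genes past the rule went in both directions. Of 32 measured genes, 7 were higher in AC29, 8 were higher in AB1 and 17 did not pass (camera adjusted p = 0.621). The guanylate binding proteins Gbp2 (at least 8.84-fold) and Gbp3 (7.86 against 6.11 in AB1, near the floor), the transcription factor Irf1 (3.23-fold) and the chemokine Cxcl10 (5.02-fold) were higher in AC29. Ifit2 (at least 6.85-fold), Ifit1 (at least 2.67-fold), the deconjugating enzyme Usp18 (at least 5.35-fold) and the transcription factor Irf9 (at least 3.58-fold) were higher in AB1. In the cytokine and chemokine list, 4 of 36 genes were higher in AC29 and 5 higher in AB1 (camera adjusted p = 0.845). The neutrophil attractant Cxcl5 (9.19 ± 0.24 against 4.28 ± 0.44, SD, n = 3; at least 8.66-fold), Il18 (at least 8.69-fold), the monocyte attractant Ccl2 (3.30-fold) and Cxcl16 (3.16-fold) were higher in AC29. Cx3cl1 (4.73-fold), Lif (2.68-fold) and Il34 (at least 1.24-fold) were higher in AB1. Csf1, the macrophage growth factor, read 11.02 ± 0.04 in AC29 and 10.39 ± 0.04 in AB1, a 1.56-fold difference (adjusted p = 0.000157) under the 2-fold minimum, and Csf2 and Il6 were not above the floor in either line. In the immune checkpoint list, 3 of 33 genes were higher in AC29 and 4 in AB1 (camera adjusted p = 0.621). Tgfb2, which encodes a transforming growth factor, was at least 16.9-fold higher in AC29, and the prostaglandin enzymes Ptgs2 (6.59-fold) and Ptges (13.2-fold) were higher in AB1. Cd274, which encodes the ligand PD-L1, was not above the floor in either line.

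**Figure D4:**
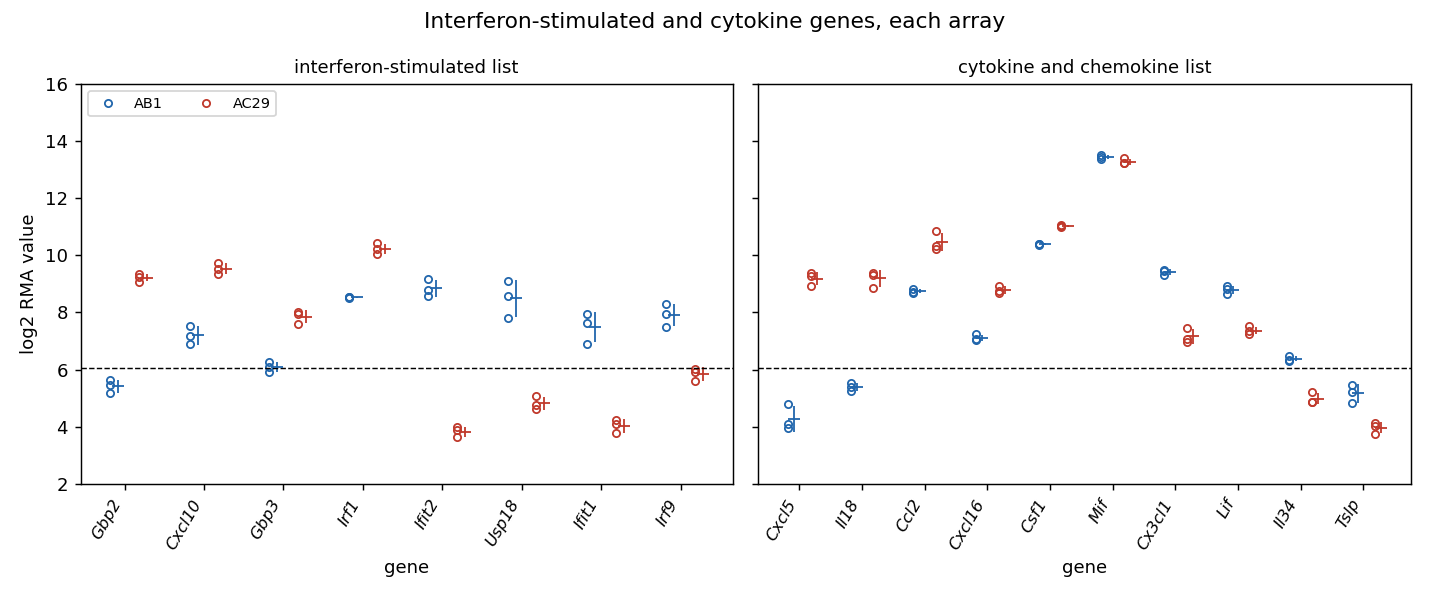
Log2 RMA value of each array (open circles), with the mean and SD of 3 arrays beside them, for named interferon-stimulated genes (left) and cytokine and chemokine genes (right) in AB1 (blue) and AC29 (red); the dashed line is the floor of 6.07. Gbp2 averages 9.22 in AC29 and 5.42 in AB1, and Ifit2 averages 3.84 in AC29 and 8.85 in AB1.

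Most of the p53 target genes past the rule were higher in AB1. Of 25 measured p53 target genes, 11 were higher in AB1 and 2 higher in AC29 (camera adjusted p = 1.60e-05 toward AB1; adjusted p = 0.119 with an estimated correlation). Ccng1, which encodes cyclin G1, was 5.03-fold (12.02 ± 0.07 against 9.69 ± 0.21, SD, n = 3) and the RNA binding protein Zmat3 4.82-fold higher in AB1, and Pmaip1, which promotes apoptosis, at least 1.86-fold. Perp, a desmosome protein also found in epithelia, was at least 5.12-fold higher in AC29, and Ddit4l at least 1.88-fold. Of 15 genes known for alterations in mesothelioma, 2 passed the rule, both higher in AB1 (camera adjusted p = 0.326): Mdm2, the ubiquitin ligase for p53, at 2.70-fold and Sav1, a Hippo pathway scaffold, at 2.01-fold. Sav1 did not pass with quantile normalization or without AB1 replicate 5 or AC29 replicate 14, which leaves 1 gene. Cdkn2a, Cdkn2b and Tert were not above the floor in either line, and Mtap read 6.27 in AB1 and 6.49 in AC29. Bap1, Nf2 (9.35 and 8.95), Setd2, Lats1, Lats2, Rassf1, Ddx3x, Ccnd1 and Myc did not pass the rule by their brightest probe sets, although another probe set did for Ccnd1 (-1.22) and Lats2 (-1.62); the widest of these differences were those of Myc at -0.82 and Ccnd1 at -0.73.

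Of 29 genes tied to the Hippo pathway, 5 were higher in AB1 and 3 in AC29 (camera adjusted p = 0.621). The secreted YAP target Ccn2 was 24.8-fold (13.38 ± 0.11 against 8.75 ± 0.12, SD, n = 3) and Ankrd1 7.69-fold higher in AB1, while Ccn1 read 12.01 and 11.04 and stayed under the 2-fold minimum by its brightest probe set, with another at -1.08. Wwc1, an upstream regulator, was 9.71-fold higher in AC29. Growth factors and their receptors leaned toward AB1, with 12 of 36 higher in AB1 and 5 higher in AC29 (camera adjusted p = 0.0459). The adjusted p = 0.612 with an estimated correlation, and it was 0.117 on ranks, 0.0515 without AC29 replicate 13 and 0.0720 without AC29 replicate 14. The epidermal growth factor ligands Ereg (14.3-fold) and Hbegf (7.19-fold) and the receptor Fgfr1 (5.62-fold) were higher in AB1, and the receptors Flt4 (at least 7.95-fold), Fgfr3 (8.70 against 6.08 in AB1, near the floor) and Met (3.85-fold) were higher in AC29. None of 35 cell cycle genes passed the rule in limma in either direction (camera adjusted p = 0.122), the brightest signal being that of Pcna at 13.46 and 13.40.

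Some sterol synthesis genes were higher in AC29, and some genes of the unfolded protein response were higher in AB1. Of 18 cholesterol synthesis genes, 4 were higher in AC29 and none in AB1 (camera adjusted p = 4.05e-05; adjusted p = 0.612 with an estimated correlation). The sterol carrier Stard4 was 3.03-fold (11.08 ± 0.15 against 9.48 ± 0.07, SD, n = 3), Hsd17b7 2.89-fold, the synthase Hmgcs1 2.43-fold and Cyp51 2.38-fold higher. Of 22 unfolded protein response genes, 7 were higher in AB1 and none in AC29 (camera adjusted p = 0.000272; adjusted p = 0.373 with an estimated correlation). Chac1, a glutathione-degrading enzyme, was 11.7-fold and the pseudokinase Trib3 2.88-fold higher in AB1, while the chaperones Hspa5 (13.65 in AB1 and 13.67 in AC29) and Hsp90b1 (13.31 and 13.29) did not pass. Of 19 glycolysis genes, 5 were higher in AC29 and 2 in AB1 (camera adjusted p = 0.896), with the lactate transporter Slc16a3 at 19.6-fold and the glucose transporter Slc2a3 at 7.57-fold higher in AC29 and the hexokinase Hk1 at 3.88-fold higher in AB1. Of 20 hypoxia genes, 3 were higher in AC29 and 6 in AB1 (camera adjusted p = 0.354), including Vldlr (10.96 in AB1 and 6.01, near the floor, in AC29) and Vegfa at 2.93-fold in AB1. Of 28 oxidative phosphorylation genes, only Cox5b passed, 2.18-fold higher in AB1 (camera adjusted p = 0.564), and not on the mean of its probe sets (-0.78). In the list of genes controlled by Nrf2, 3 of 21 were higher in AC29, the glutathione transferase Gsta4 at least 102-fold, Me1 3.24-fold and Hmox1 2.48-fold, and none in AB1 (camera adjusted p = 0.0506). That list passed with quantile normalization (0.0436), arrays centred on their median (0.0462), the mean of probe sets (0.0318) and without AB1 replicate 4 (0.0385) or 6 (0.0393), but not with an estimated correlation (0.612).

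Dkk2, Dkk3, Grem1 and Bmp2, which encode secreted proteins, were higher in AB1, while neither the Wnt list nor the TGF-beta and BMP list passed camera. Of 31 Wnt genes, 4 were higher in AB1, among them Dkk2 (at least 23.6-fold) and Dkk3 (at least 18.8-fold), and 3 were higher in AC29, among them the ligands Wnt10a (3.93-fold) and Wnt4 (3.50-fold), with a camera adjusted p of 0.998. Of 30 genes of the TGF-beta and BMP pathways, 8 were higher in AB1 and 3 in AC29 (camera adjusted p = 0.621). Bmp2 was at least 21.8-fold (10.52 ± 0.07 against 3.69 ± 0.19, SD, n = 3) and Fst, which encodes the activin antagonist follistatin, at least 17.5-fold higher in AB1, beside Grem1. Bmp4 was 5.22-fold and the inhibitory Smad6 5.61-fold higher in AC29.

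Most markers of macrophages, lymphocytes and endothelium were not above the floor in either line, while 5 fibroblast markers were higher in AC29. Of 17 macrophage genes, 1 passed, Cd14 at 3.39-fold higher in AB1, and 11 were not above the floor in either line (camera adjusted p = 0.907). None of 15 lymphocyte genes passed in limma (camera adjusted p = 0.629), with 12 not above the floor in either line. Of 16 endothelial genes, 12 were not above it and 1 passed (camera adjusted p = 0.907). That gene was Esam, higher in AC29 at 10.59 against 6.17, near the floor, in AB1. Of 15 fibroblast genes, which share Pdgfra, Pdgfrb, Dcn, Lum, Fbln1 and Thy1 with the lists above, 5 were higher in AC29, including Dcn and Scara5 (at least 6.32-fold), and 1 in AB1 (camera adjusted p = 0.122). Of 14 muscle genes, 2 were higher in AC29 and 1 in AB1, Actg2 at least 10.4-fold (camera adjusted p = 0.621). Of 15 neural genes, 5 were higher in AB1, including the growth cone protein Gap43 at least 20.7-fold, and 2 in AC29, including Mbp at least 8.28-fold (camera adjusted p = 0.295). The labels give both lines as female. Xist, the RNA of the inactive X chromosome, read 9.38 ± 0.47 (SD, n = 3) in AC29 and 5.60 ± 0.22 in AB1, at least 9.87-fold, and the Y-linked genes Uty, Kdm5d and Eif2s3y were not above the floor in either line.

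Over the 36 lists, the numbers of genes called higher in each line adjusted over the list alone were the same as those adjusted over all genes. Of 35 lists tested, 6 passed camera with its preset correlation, 2 toward AC29 and 4 toward AB1, and none passed with an estimated correlation. The median, the mean and the camera direction did not all have the same sign for the collagen and matrix, adhesion, MHC class II, interferon-stimulated, glycolysis, Wnt and endothelial lists.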

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

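The tests on H2-K1 and H2-D1 below were chosen after their values were seen; the count over other splits of the arrays was planned before the data were examined.

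Signal outside the genes compared was found in probe sets that the annotation leaves unnamed or shares among genes. Among probe sets with no symbol, 220 passed the call rule and were above the floor in at least 1 line, and among probe sets with several symbols 74 did. The poly-A control transcripts, which are added during labelling, averaged 7.58 on AC29 replicate 15 against 8.25 to 8.46 on the other arrays, a difference of -0.76 from their mean. The number of called genes without that replicate was 1990.

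The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1991 called genes and was the only 1 of the 10 with as many; the highest of the other splits gave 0. Each of the other splits mixes the lines, which puts the line difference into the residual spread, so few calls could follow. The contrast therefore says nothing about chance or batch.

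H2-K1 and H2-D1, the class I heavy chains, were lower in AC29 by the probe sets that stand for them, by all 3 of the H2-K1 probe sets above the floor and by 7 of 8 for H2-D1, the lowest difference being -4.12. BALB/c and CBA mice carry different H-2 haplotypes, and variants of these genes under the probes may set the values: the remaining H2-D1 probe set went from 4.32 in AB1 to 11.50 in AC29, a difference of 7.18 past the call rule and of at least 5.42 against the floor, under which the AB1 arrays lay, which a change in the amount of 1 transcript alone would not give. Variants in strain are therefore a candidate explanation for at least part of the pattern. Lower amounts of both transcripts in AC29, a biological difference between the lines, cannot be told apart from it, because the probe sets of H2-D1 move in opposite directions, those of H2-K1, though all lower, may also lie on variants, which were not analysed here, and no protein was measured. Most of the probe sets counted above carry the mark for cross-hybridisation, so they are not independent readings of a single gene. Probe sets with several symbols, not counted above, do not settle the question. The probe set shared by H2-K1 and H2-D1 read 9.98 in AB1 and 10.46 in AC29. That shared by H2-Q5 and H2-K1 read 7.34 in AB1 and 6.86 in AC29, and neither passed the rule. Some shared by other class I genes were higher in AC29 past the rule. That of H2-Q9 and H2-Q7 read 4.73 in AB1 and 8.42 in AC29. A probe set of H2-T9, H2-T22 and H2-T10 read 9.20 in AB1 and 10.99 in AC29. The rest of those above the floor did not pass in either direction. Over all called genes, only 2 of 1423 other probe sets above the floor passed the rule in the opposite direction, the H2-D1 probe set that was higher in AC29 and 1 of Rabgap1l, a gene singled out after its values were seen.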

How the results depend on the processing

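The alternatives were planned before the data were examined. No paired analysis was possible because the sample numbers of the lines are not shared. The count of 1991 called genes (932 higher in AC29, 1059 higher in AB1) stayed within 1.5 times under quantile normalization, both centrings, the floor filter, the mean of probe sets, the cross-hybridisation filter, trend and robust settings, array weights and the unmoderated fit, where 1585 to 1991 of the called genes were shared and 0 were called in the opposite direction. Limma's treat called 1237 (565 and 672), every probe set on its own 3914 (1895 and 2019), no minimum difference 7105 (3475 and 3630), and an adjusted p under 0.01 with at least 4-fold 723 (335 and 388); these follow from the thresholds or the number of features tested. With each array left out in turn the count was 1990 to 2029 (897 to 986 higher in AC29, 1024 to 1095 higher in AB1). The filter at the median gene left 619 higher in AC29, with fewer genes tested.

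Of the gene lists, 6 passed in the main test, 0 with an estimated correlation, 27 with fry in a single direction and 34 with fry in either direction, which do not compare a list with other genes. With an estimated correlation the adjusted p was 0.0588 (mesothelial), 0.190 (mesenchymal), 0.119 (p53 target), 0.373 (unfolded protein), 0.612 (cholesterol synthesis) and 0.612 (growth factor receptor). The last was also 0.117 on ranks and 0.148 with the floor filter; the cause was not tested. With each array left out in turn 5 to 7 lists passed, and the adjusted p of the growth factor receptor list was 0.0183 to 0.0720 (0.0515 without AC29 replicate 13, 0.0720 without AC29 replicate 14). The Wnt and endothelial lists reversed direction under fry in a single direction (adjusted p = 0.00318 and 0.00904). Directions that differed elsewhere, at most 2 lists per setting, were of lists past the threshold in neither setting. Of 2697 alternative values of named genes, with changes of size that kept the call status not counted, 44 lost a call and 21 gained one. Those that lost a call include Sav1, Cd44, Lif, Tap1, Cox5b and Impact, and other probe sets of Ercc1 (-0.22), Mbp (0.09), Gata6 (0.76) and Fgfr3 (0.82). Another 2 had the opposite sign, a probe set of Fbln1 (-0.14, adjusted p = 0.357, not a call) and a probe set of H2-D1 (7.18, at least 5.42 against the floor, a call), and 36 changed sign without a call in either setting. The correlations moved with the floor filter to a lowest of 0.990 within a line and a highest of 0.824 between lines. The floor was 5.68 at the 90th and 7.23 at the 99th percentile, with 504 and 825 in place of 631 called genes in which a single line was not above it, and 47 and 316 in place of 84 in which neither line was; signal over this background limits the folds of dim genes.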

Other observations

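The tests below on chromosomes and on neighbouring genes were chosen after the values were seen, with a single exception. The criterion for the count over 4 equal parts of the most shifted chromosomes was written before, but these chromosomes were picked by their values. Genes named in these tests outside the naming rule, among them Minpp1, Papss2, Atad1, Sgms1, Hacd4, Klhl9 and Hivep2, were also chosen after their values were seen.

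Hoxa11, Hoxd9 and Hoxd10 were higher in AB1. Of 30 measured genes in the homeobox list, 5 were higher in AB1 and 1 in AC29 (camera adjusted p = 0.234). Hoxa11 was at least 11.5-fold (9.60 ± 0.14 against 5.39 ± 0.20, SD, n = 3), Hoxd9 5.63-fold, Hoxd10 at least 4.71-fold and Hoxc4 2.21-fold higher in AB1, and Hoxb2 was 2.24-fold higher in AC29. Of 27 lineage transcription factors, 5 were higher in AB1 and 2 in AC29 (camera adjusted p = 0.122). Etv5 (11.8-fold) and Etv4 (4.43-fold), which respond to growth factor signalling in many cells, and Emx2 (at least 4.59-fold) were higher in AB1, and Gata6 was 3.45-fold higher in AC29 beside Wt1.

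Genes of drug handling gave some of the widest differences. Of 23 measured genes, 3 were higher in AC29 and 3 in AB1 (camera adjusted p = 0.158). The efflux pump Abcg2 (at least 31.8-fold; 11.06 ± 0.12 against 4.95 ± 0.40, SD, n = 3), the oxidase Cyp1b1 (at least 33.7-fold) and the dehydrogenase Aldh1a1 (at least 19.5-fold) were higher in AC29. Ercc1, which acts in the repair of platinum adducts, was 17.6-fold higher in AB1 (12.59 ± 0.08 against 8.46 ± 0.20), and the pump Abcb1a at least 2.92-fold. Of 25 imprinted genes, 3 were higher in AC29, including Impact at 2.45-fold, and 2 in AB1, including Sgce at least 5.02-fold (camera adjusted p = 0.621). Of 20 cancer-germline genes, 18 were not above the floor in either line and 1 passed, Piwil2 at least 13.4-fold higher in AC29 (camera adjusted p = 0.564).

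Genes of some chromosomes were shifted together in both directions: among 7522 genes with a mean of at least 8 in a line, the median difference was -0.50 on chromosome 7, where 84.7% of 478 genes were lower in AC29, -0.49 on chromosome 14 and -0.34 on chromosome 12, and it was 0.27 on chromosome 5, 0.24 on 11, 0.23 on 17, 0.19 on 4 and 0.16 on 9, against -0.01 over the genome. A technical dependence on expression level was tested against 10000 random gene sets matched on mean expression, and 13 of 20 chromosomes lay outside them at an adjusted p under 0.05, so that level alone does not explain the shift. On chromosomes 7, 14 and 12, a few local clusters of genes do not explain the shift either. There, 12 of 12 parts, 4 from each, were shifted by at least 0.1 to the same side. These chromosomes were picked as the most shifted, which favours such a count, and no chromosome shifted toward AC29 was divided. Different DNA copy number of whole chromosomes, a biological cause, would give shifts of this kind, but DNA was not analysed here and the shift of -0.50 leaves that open.

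Among the 7522 genes with a mean of at least 8 in a line, those with signal in a single line followed each other along chromosomes more often than by chance. Such genes, 128 in AB1 and 112 in AC29, formed 15 pairs with no other of the 7522 between them, among them Krt7 with Krt8 and Col4a1 with Col4a2, against at most 12 in 10000 shuffled orders (permutation p = 1e-04, the smallest possible), so random placement does not explain them. Loss of DNA segments in a line was tested with the 7 genes that lie between pair members and read at least 7 in the line with signal: 3 (Papss2, Ifit1 and Hoxd11) were not above the floor in the other line, against a share of 4.57% among all genes of that signal range, a count that met the criterion written against lost segments. The other 4 (Hivep2, Krt78, Krt81 and Krt83) read 7.05 to 7.64 in that line, but they lie in only 2 of the 15 pairs and, like the 3, not far from the 99th percentile of the receptor probe sets at 7.23, so lost segments were left open, a choice made after this result was seen. Of the 3, Ifit1 lies beside Ifit2 and Hoxd11 between Hoxd13 and Hoxd10, so the share over all genes is not a like baseline for them. Regulation shared by neighbouring genes of a family was not tested. At a single place, all 4 probe sets of Minpp1, Papss2 and Atad1 that were at least 4-fold over the floor in AB1 were not above it in AC29 (Minpp1 9.71 and 3.86, Atad1 9.85 and 3.80), while the neighbour Sgms1 kept signal at 9.07 and 7.98; a lost segment and shared silencing would both give this, and the genes were picked because they show it.

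Hacd4 (8.44 in AB1 and 4.72 in AC29) and Klhl9 (9.09 and 4.45) lie near Cdkn2a, which was not above the floor in either line. Plaa (10.75 and 10.58), of the same region, kept signal in AC29, while Mtap (6.27 and 6.49) was too close to the floor to tell. Gene order was taken from the mouse assembly GRCm38.p6. DNA sequencing or copy number arrays of both lines would separate lost DNA from silencing at these places.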
